A study of Xenopus laevis with 6 samples.

How the data were processed

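Polyadenylated RNA from 6 single whole embryos of Xenopus laevis at stage 11.5 was sequenced, 3 of them uninjected and 3 injected with 100 pg of dkk mRNA at the 2-cell stage, per the labels' protocols. Libraries were made with an Illumina TruSeq RNA kit from total RNA extracted with Trizol, 1 embryo per library. The series' design text states that each control and dkk embryo of a replicate were siblings and that replicates came from different matings, so that the replicate number pairs the embryos. No embryo injected with another mRNA was analysed here.

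The authors deposited a table of raw read counts per gene for each embryo, with no normalization. TopHat2, SAMtools and HTSeq are named in the submitters' processing notes; their versions, settings, genome build and gene annotation are not given in the sources used here. Gene rows numbered 45099, of which 35909 had a read in at least 1 library. The rows that name no gene were left out of library sizes and tests: reads outside genes made up 7.58% to 8.80% of a library's counted reads, ambiguous reads 2.03% to 2.19% and reads with more than 1 alignment 15.9% to 17.6%. Since reads with several alignments were not counted, the near-identical L and S copies of a gene may lose reads or share them unequally, and the level of a single copy is uncertain to that extent. Bare identifiers stood in 27771 rows, and 12007 rows matched a symbol of a reference table for the assembly Xenopus_laevis_v10.1, used for names alone. Of the genes to be named whatever their result, ventx2, chrd and otx2 had no row under those names.

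The authors also deposited a table of 97 genes from their own comparison. Per the file headers it holds a baseMean, a signal that is the mean of normalized counts over all embryos, a log2 fold change with its standard error, a test score (the log2 fold change divided by its standard error), a p-value and an adjusted p-value. Its model is not given in the sources used here. The baseMean values equalled the mean counts scaled by DESeq2 size factors computed here. An unpaired DESeq2 fit with a shrinkage prior gave log2 fold changes with a median absolute difference of 0.00539 from the authors' values.

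Reads in genes numbered 17460820 to 19880568 per library. Between 25.6% and 28.2% of counted reads were assigned to no gene, with ambiguous reads and reads with more than 1 alignment among them. The 10 most abundant genes held 3.14% to 3.89% of the reads in genes. At any depth, a count of 0 in a library leaves room for an expected count of up to about 3 reads (95% upper limit for Poisson counts). Each library holds a different embryo, and all were kept as separate replicates. The pairing was checked as the correlation of deviations from group means. It was 0.674, 0.552 and 0.622 within mating pairs 1 to 3 and at most -0.152 between different pairs. Deviations cancel out within each group, so positive values within pairs make those between pairs negative on average. The negative values are therefore no separate evidence for the pairing. The biological coefficient of variation was 0.206 with the mating pair as a block and 0.389 without. With 1 embryo per group and mating, p-values measure the spread of the dkk effect between these 3 sibling pairs.

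Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with its default minimum count of 10 and total of 15, robust dispersion estimates, the quasi-likelihood F test (glmQLFit, glmQLFTest) and the mating pair as a block. P-values were adjusted by the Benjamini-Hochberg method over the 21643 genes left by the filter, with a threshold of 0.05. The standard errors printed are those implied by the F statistic. CPM values are counts scaled to TMM library sizes (edgeR's cpm function), and log2 ratios of single pairs used a prior count of 2. The median log2 fold change of all tested genes was -0.00131 with TMM, 0.00172 with DESeq2 size factors and 0.0227 with upper-quartile scaling. Gene lists, 19 in all, were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and adjusted over the lists.

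The design, tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. The rule named every dkk1 row, the 10 largest rises and falls among genes past the threshold that had a name and the same sign in all pairs, up to 4 members of each list with the smallest p, and 13 genes of axis formation whatever their result. Named after their values were seen were tcf7.S, rspo2.L, rspo2.S, mespb.L, mespb.S, tcf7l1.L, foxc1.S, cdx1.L, rara.S and hoxd1.S. One gene that the rule would name is not reported here.

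Alternatives were a fit without the block, DESeq2 size factors and upper-quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, a test against a fold of 1.2 (glmTreat), L and S copies summed, each mating pair left out, camera with an estimated correlation and fry. Chosen after seeing the data were the unpaired DESeq2 fit with a shrinkage prior, the lists without dkk1.S and the between-pair agreement under each alternative.

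Exploratory paired and unpaired fits with edgeR and DESeq2 were looked at before the final runs, and the patterns weighed in the closing part were picked from an edgeR fit among them. The 2 smaller stress sets, of p53 targets and of heat shock, unfolded protein and immediate early genes, were written after the counts had been opened. The computation was tested on simulated data. For the comparison of dkk with control over 21643 simulated genes with trended dispersion, the paired fit recovered 53 of 100 genes changed by 1 and 90 of 100 changed by 2 on the log2 scale, with 2 false among 145 calls. With gene-wise dispersion it recovered 42 and 90 of 100, with 19 false among 151 calls (12.6%), above the nominal 5%. The unpaired fit recovered 0 and 21 of 100 with trended dispersion. The simulation kept the pair effects of the data and gave every pair the same dkk effect. A loss in the unpaired fit was thus built in and is no evidence for the paired fit. In the list test 6 of 200 unchanged lists had a p under 0.05. The simulated genes were drawn independently, so this cannot show how the list test behaves when members of a list correlate. For the ratio of L to S copies 85 of 100 changed pairs were recovered, with 10 false among 95 calls, also above the nominal share. Figures were drawn with matplotlib 3.10.9.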

Results

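Whole embryos of the African clawed frog Xenopus laevis were profiled singly at stage 11.5, during gastrulation, by sequencing of polyadenylated RNA. Control embryos (n = 3) were left uninjected. The dkk embryos (n = 3) had received 100 pg of mRNA for Dickkopf, a secreted antagonist that blocks the Wnt co-receptors of the Lrp5/6 class, at the 2-cell stage. Each dkk embryo had a control sibling from the same mating, and the 3 sibling pairs came from 3 different mating pairs. Xenopus laevis carries many genes in 2 copies from its L and S subgenomes, and each copy (homeolog) is named here with its suffix. Reads assigned to genes numbered 17460820, 19481603 and 18772049 in controls 1 to 3 and 18947192, 19384110 and 19880568 in their dkk siblings. Between 30087 and 31271 genes had at least 1 read. The comparison asked which genes respond at gastrulation to a knockdown of canonical Wnt/β-catenin signalling, in which ligand binding stabilises β-catenin and switches on Tcf target genes.

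Both copies of dkk1 were read in every embryo; the labels name the injected mRNA only as dkk, and the copy it derives from was not tested. The S copy, dkk1.S, rose from 15.2 ± 4.18 CPM (SD, n = 3) in controls to 570 ± 136 CPM in dkk embryos, a 37.5-fold difference (log2 fold change 5.23 ± 0.26, SE; adjusted p = 0.00194, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its read counts were 204, 366 and 274 in controls 1 to 3 and 9526, 8491 and 15993 in the dkk siblings. The L copy, dkk1.L, was read at 16.1 ± 2.69 CPM in controls and 4.55 ± 3.91 CPM in dkk embryos (log2 fold change -2.08 ± 0.41, SE). It was lower in 3 of 3 pairs but did not pass the threshold (adjusted p = 0.152, edgeR with Benjamini-Hochberg adjustment). Counts of dkk1.L were 223, 327 and 346 in controls and 45, 39 and 200 in their siblings. The counts do not separate any injected mRNA from the embryo's own dkk1.S transcript.

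In the paired fit of all embryos more genes fell than rose in dkk embryos. Among genes with a symbol, deep falls were in sp5.S, a transcription factor gene induced by Wnt, in kremen2.L, which encodes a Dickkopf receptor, and in the anterior Hox genes hoxb1.S and hoxd1.L, followed by axin2.L, axin2.S, znf703.L, fzd10.S and the lipoprotein lipase copy lpl.S. Their log2 fold changes ran from -6.69 for sp5.S to -3.19 for lpl.S. The other copy of that gene, lpl.L, stood at -0.22 and did not pass the threshold. The largest rise, 5.66, was in Xelaev18038693m.g, a gene known only by that identifier. After dkk1.S, the 9 next largest rises among genes with a symbol ran from 2.15 for col5a1-like.S, 1.90 for rbl2-like.L and 1.54 for eda2r-like.1, through ccng1.S, ccng1.L, cebpa.1 and hhex.L, to 1.00 for fzd8.L and 0.95 for fzd8.S. The other copy of col5a1-like, col5a1-like.L, stood at 0.89 and did not pass the threshold. Over all genes, 124 of 21643 tested passed an adjusted p of 0.05 (edgeR with Benjamini-Hochberg adjustment). Of these, 101 fell, 91 of them over 2-fold, and 23 rose, 14 of them over 2-fold. All 124 had the same sign in the 3 pairs, which a test on paired differences favours. An unadjusted p under 0.05 was met by 1693 genes, and 49 of the 124 carry only a bare identifier. The count depended on the pairing and on single pairs: it was 14 without the mating pair as a block, 58 without pair 2 and 659 without pair 3. Without pair 3 rises and falls were even, at 332 and 327. The calls of lpl.S (adjusted p = 0.151) and col5a1-like.S (0.152) were lost without pair 2 (edgeR with Benjamini-Hochberg adjustment).

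**Figure D1:**
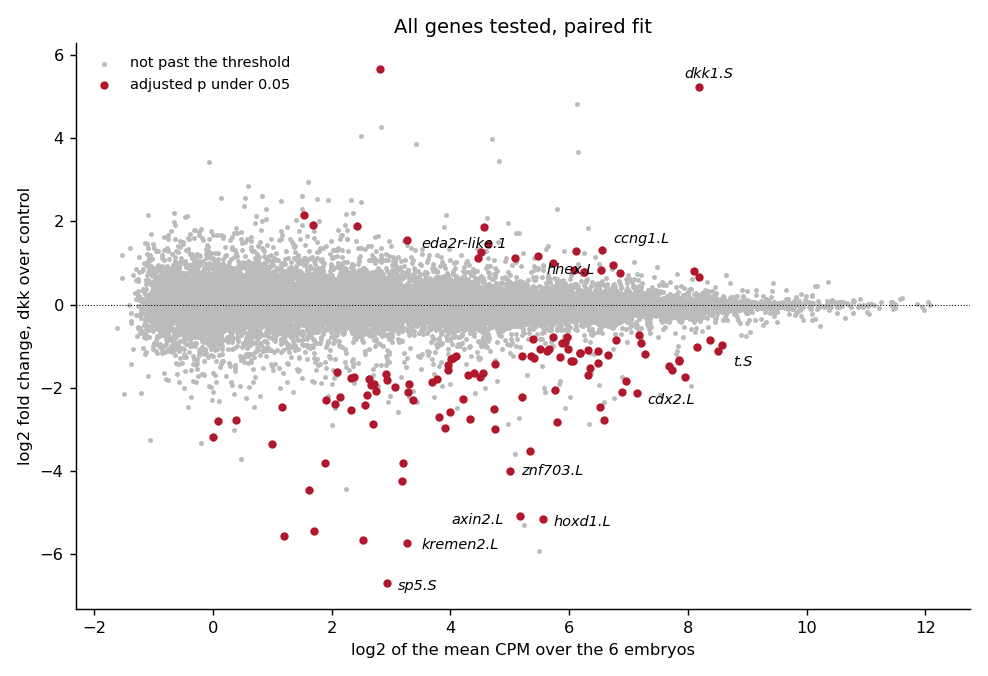
Log2 fold change of dkk over control embryos against the log2 of the mean CPM over the 6 embryos, for all 21643 genes tested. Red points are the 124 genes past an adjusted p of 0.05 in the paired edgeR fit, 101 of them below 0, and the labelled genes are named in the text.

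Some genes that canonical Wnt signalling switches on in many vertebrate tissues fell in dkk embryos. axin2, a scaffold of the β-catenin destruction complex and a feedback inhibitor of the pathway, fell in both copies, with axin2.L going from 69.4 ± 21.5 CPM to 2.52 ± 2.60 CPM (SD, n = 3 each; log2 fold change -5.09 ± 0.42, SE) and axin2.S changing by -4.46 ± 0.63. sp5.S fell by 6.69 on the log2 scale, from 393, 175 and 251 reads in controls 1 to 3 to 3, 2 and 3 reads in the dkk siblings. Its homeolog sp5.L went from 73.4 ± 7.34 CPM to 2.35 ± 2.66 CPM, but this difference did not pass the threshold (log2 fold change -5.30 ± 0.70; adjusted p = 0.141, edgeR with Benjamini-Hochberg adjustment). The related sp5l.L and sp5l.S fell by less, to log2 fold changes of -0.98 and -0.84, and tcf7.S, which encodes a β-catenin partner on DNA, fell by 1.43 on the log2 scale. In the Wnt feedback list, 6 of 21 tested members fell, 0 rose and 15 did not pass. Adjusted over the list alone, 12 fell and 0 rose. As a group the list lay below the other genes (camera, adjusted p = 7.45e-19 with a preset correlation; adjusted p = 0.168 with an estimated correlation). Without pair 2 the calls of axin2.S (adjusted p = 0.164), sp5l.S (0.0816) and tcf7.S (0.0857) were lost, and without pair 3 that of axin2.S (0.0532, edgeR with Benjamini-Hochberg adjustment).

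Genes of the Wnt pathway itself moved in both directions. kremen2 fell in both copies, with log2 fold changes of -5.74 for kremen2.L and -2.30 for kremen2.S. fzd10.S, a Frizzled receptor gene, fell from 73.5 ± 10.9 CPM to 7.43 ± 5.38 CPM (SD, n = 3), and both copies of rspo2, which encodes an R-spondin that amplifies Wnt signalling, fell to log2 fold changes of -1.79 for rspo2.L and -2.41 for rspo2.S. The Frizzled copies fzd8.L and fzd8.S rose by 1.00 and 0.95, and tcf7l1.L, which encodes a Tcf repressor, rose by 0.67. Of 68 tested pathway members, 7 fell, 4 rose and 57 did not pass. Among the 4 was dkk1.S, whose reads may come from the injected mRNA. Adjusted over the list alone, 14 fell and 8 rose. The list as a whole lay lower (camera, adjusted p = 0.0241 with a preset correlation; adjusted p = 0.401 with an estimated correlation), and this was lost without pair 1 (0.0802) or pair 3 (0.253). Copies of the gastrula Wnt ligand wnt8a did not pass the threshold: wnt8a.L was at 82.0 ± 7.28 CPM in controls and 79.2 ± 13.6 CPM in dkk embryos (log2 fold change -0.06 ± 0.16), and wnt8a.S at 63.4 ± 9.41 CPM and 61.8 ± 10.8 CPM (-0.04 ± 0.18). Their adjusted p-values were 0.963 and 0.985 (edgeR with Benjamini-Hochberg adjustment), and both signs turned without pair 3, to 0.13 and 0.22. The calls of fzd8.L, fzd8.S, tcf7l1.L, rspo2.S and kremen2.S were lost without pair 2, and that of tcf7l1.L also without pair 1.

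**Figure D2:**
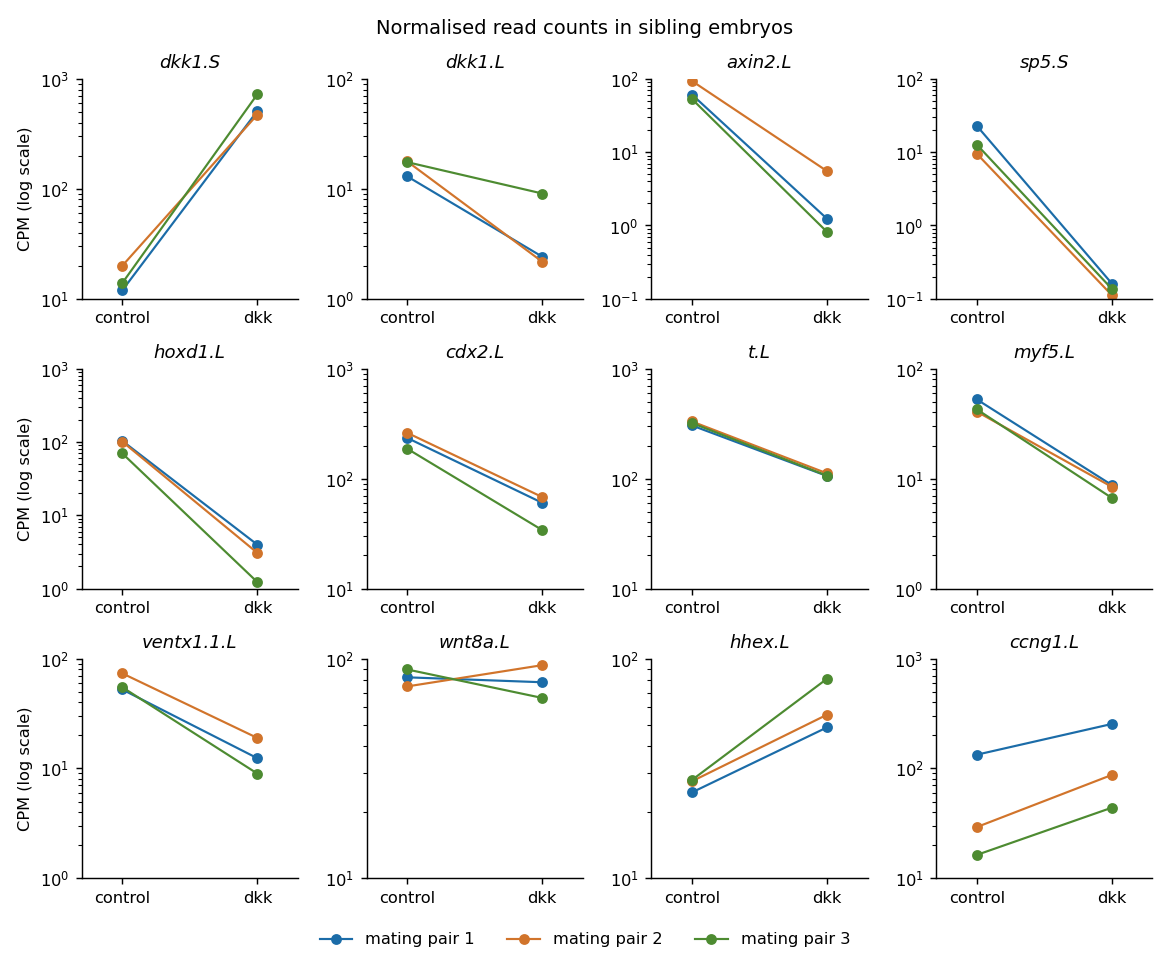
CPM on a log axis in control and dkk embryos for 12 genes, each line joining the 2 siblings of 1 mating pair. dkk1.S rises in all 3 pairs, axin2.L, sp5.S, hoxd1.L, cdx2.L, t.L, myf5.L and ventx1.1.L fall in all 3, hhex.L and ccng1.L rise in all 3, wnt8a.L goes up in 1 pair and down in 2, and dkk1.L, lower in all 3, did not pass the threshold.

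Several genes of ventrolateral and posterior mesoderm fell, while most members of their list did not pass the threshold. Brachyury, the pan-mesodermal T-box gene, went from 319 ± 13.4 CPM to 108 ± 3.26 CPM in its L copy (t.L; SD, n = 3; log2 fold change -1.56 ± 0.09, SE) and from 501 ± 34.8 CPM to 230 ± 20.0 CPM in its S copy (t.S; -1.13 ± 0.09). The muscle determination gene myf5 fell in both copies (myf5.L -2.51, myf5.S -1.74), and so did the segmentation gene mespb (mespb.L -2.59, mespb.S -1.58). The caudal-type genes, which pattern the posterior body, fell by 2.22 and 1.33 in cdx1.L and cdx1.S and by 2.12 and 1.53 in cdx2.L and cdx2.S on the log2 scale, and the forkhead gene foxc1.S fell by 1.07. Among 46 tested members of this list, 14 fell, 0 rose and 32 did not pass. Adjusted over the list alone, 26 fell and 1 rose, and 20 of the 46 also stand in another list. The group test gave an adjusted p of 2.10e-24 (camera, preset correlation; adjusted p = 0.273 with an estimated correlation and 0.117 with fry). Several large differences were not past the threshold, each lower in 3 of 3 pairs: msgn1.L at -2.88 ± 0.37 (adjusted p = 0.0517), msgn1.S at -3.60 ± 0.68 (0.294), myod1.L at -1.95 ± 0.31 (0.0517), myod1.S at -2.11 ± 0.59 (0.517), cdx4.L at -1.74 ± 0.57 (0.631) and cdx4.S at -1.65 ± 0.49 (0.534), all from edgeR with Benjamini-Hochberg adjustment. In these 6 the lowest ratio was that of pair 3, for example -3.20 against -0.93 and -1.23 in cdx4.L. Without pair 2 the calls of myf5.S, mespb.L, mespb.S, cdx1.L, rspo2.S and foxc1.S were lost, and that of foxc1.S also without pair 1.

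Several posterior neural genes and genes of the retinoic acid response fell as well, with some in both lists. hoxd1.L fell from 91.7 ± 18.8 CPM to 2.75 ± 1.40 CPM (SD, n = 3; log2 fold change -5.14 ± 0.24, SE), and hoxb1.S from 4.49 ± 2.89 CPM to 0.0921 ± 0.116 CPM. Both belong to the 3' part of their Hox clusters, which opens first in development. znf703, a zinc finger gene, fell in both copies (adjusted p = 0.000175 each, edgeR with Benjamini-Hochberg adjustment). znf703.L went from 60.5 ± 11.8 CPM to 3.89 ± 1.47 CPM and znf703.S from 96.6 ± 16.5 CPM to 13.8 ± 2.84 CPM. The retinoic acid receptor copy rara.S fell from 67.1 ± 11.6 CPM to 31.7 ± 9.35 CPM. Its other copy rara.L had a log2 fold change of -0.03 and did not pass. hoxd1.S, at 88.7 ± 14.5 CPM in controls and 1.68 ± 1.33 CPM in dkk embryos, missed the threshold (-5.91 ± 0.59; adjusted p = 0.0588). In the posterior neural list 8 of 32 tested members fell, 0 rose and 24 did not pass, with 17 lower and 1 higher when adjusted over the list alone. For the retinoic acid list 6 of 22 fell, 0 rose and 16 did not pass, with 10 lower and 1 higher when adjusted over the list alone. The retinoic acid list's median log2 fold change was -0.24 and its mean -1.53, so members with large falls, among them hoxd1.L and znf703.L, pull the mean down. The list's median was -0.525, -0.709 and -0.0817 in pairs 1 to 3. Members shared with another list numbered 14 of 32 and 7 of 22. The camera test gave adjusted p-values of 2.12e-17 and 4.42e-11 with a preset correlation. Adjusted p = 0.193 and adjusted p = 0.168 with an estimated correlation, in the same order. The posterior marker gbx2.2.S, at 2.61 ± 0.951 CPM and 2.41 ± 0.596 CPM, had a log2 fold change of -0.08 (adjusted p = 0.979, edgeR with Benjamini-Hochberg adjustment), which turned to 0.13 without pair 2; the call of rara.S was lost without that pair. None of the 15 tested anterior neural genes passed with edgeR, 1 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and the list test was not past the threshold (camera, adjusted p = 0.261); without pair 2 it gave 0.0471.

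Among genes of ventral fate and Bmp signalling, the ventralising homeobox genes ventx1.1 and ventx1.2 fell in every tested copy. ventx1.1.L went from 60.2 ± 11.5 CPM to 13.4 ± 5.06 CPM (SD, n = 3; log2 fold change -2.21 ± 0.18, SE), and ventx1.1.S, ventx1.2.L and ventx1.2.S changed by -2.06, -1.17 and -1.07. They were the 4 that fell among 28 tested members; 0 rose and 24 did not pass. Adjusted over the list alone, 8 fell and 3 rose. The homeobox copy msx2.L, at a mean of 103 CPM in controls and 26.1 CPM in dkk embryos, did not pass (-2.22 ± 0.38, SE; adjusted p = 0.158, edgeR with Benjamini-Hochberg adjustment). The list's median log2 fold change was 0.01 and its mean -0.41, so they differ in sign. Its lower position (camera, adjusted p = 0.0279; adjusted p = 0.754 with an estimated correlation) became a higher one without pair 3, at an adjusted p of 0.413. The calls of ventx1.2.L and ventx1.2.S were lost without pair 2 and that of ventx1.1.S without pair 3.

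Of the Notch pathway, the ligand gene dlc and the Hes family gene hes6.1 fell in both copies. hes6.1.L went from 121 ± 20.7 CPM to 37.8 ± 9.03 CPM (SD, n = 3; log2 fold change -1.69 ± 0.13, SE), with -1.22 for hes6.1.S, -0.92 for dlc.L and -2.29 for dlc.S. These 4 of 23 tested members fell, 0 rose and 19 did not pass; adjusted over the list alone, 8 fell and 0 rose. The list lay lower than other genes (camera, adjusted p = 1.32e-05; adjusted p = 0.244 with an estimated correlation). The call of dlc.L was lost without pair 2 and that of dlc.S without pair 3.

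A few genes of the dorsal organizer, the gastrula's source of Bmp and Wnt antagonists, rose. hhex.L, a homeobox gene of the anterior endomesoderm, rose from 24.6, 27.6 and 28.0 CPM in controls 1 to 3 to 48.6, 55.5 and 81.0 CPM in the dkk siblings (log2 fold change 1.17 ± 0.16, SE), and the LIM homeobox copy lhx1.S rose from 85.9 ± 12.8 CPM to 145 ± 22.0 CPM (SD, n = 3; 0.75 ± 0.10). With fzd8.L, fzd8.S and dkk1.S they made up the 5 that rose among 32 tested members, while 0 fell and 27 did not pass. The reads of dkk1.S may come from the injected mRNA, so its rise need not be a response. Its other copy dkk1.L, also tested, was lower in every pair but did not pass (log2 fold change -2.08). Adjusted over the list alone, 18 rose and 2 fell. The group lay higher (camera, adjusted p = 5.27e-17, or 7.84e-15 without dkk1.S; adjusted p = 0.197 with an estimated correlation). The organizer homeobox gene goosecoid did not pass: gsc.S had a log2 fold change of 1.19 ± 0.32 (adjusted p = 0.297) and gsc.L of 0.80 ± 0.75 (adjusted p = 0.891, edgeR with Benjamini-Hochberg adjustment). The gsc.L ratios were 0.42, -0.58 and 2.58 in pairs 1 to 3, and without pair 3 its log2 fold change was -0.07. Those of gsc.S were 0.48, 0.92 and 2.09, also highest in pair 3. Calls of hhex.L, lhx1.S, fzd8.L and fzd8.S were lost without pair 2, and that of lhx1.S also without pair 1.

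Endodermal and epidermal genes showed few changes of single genes. hhex.L was the 1 member of 35 tested endodermal genes that rose, 0 fell, and 9 rose and 1 fell when adjusted over the list alone. The endodermal list lay higher (camera, adjusted p = 0.00401; adjusted p = 0.612 with an estimated correlation), but lower, at 0.283, without pair 3. Of 35 epidermal genes, tp63.S, the epidermal p63 transcription factor, fell from 24.4 ± 10.7 CPM to 3.65 ± 1.64 CPM (SD, n = 3; log2 fold change -2.71 ± 0.24, SE). The keratin copy krt18.S rose by 0.80 on the log2 scale. Its other copy, krt18.L, stood at 0.34 and was among the 33 that did not pass. Adjusted over the list alone, 2 rose and 3 fell, and the list lay higher (camera, adjusted p = 0.0107; adjusted p = 0.555 with an estimated correlation). Without pair 2 the list's adjusted p was 0.993 and the call of krt18.S was lost.

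Genes of the neural border and neural crest, of Fgf signalling and of later, neurula-stage tissues gave no single call with edgeR. In the neural border list 0 of 25 tested passed, 3 higher and 6 lower had an unadjusted p under 0.05, DESeq2 called 4 lower and limma-voom 0. It lay lower (camera, adjusted p = 0.0354; adjusted p = 0.5003 with an estimated correlation), which was lost without pair 3 (0.182). For Fgf signalling 0 of 29 passed, 2 higher and 3 lower had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and the list was not past the threshold (camera, adjusted p = 0.725). Of 21 neurula genes 0 passed, 5 higher had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The neurula list lay higher (camera, adjusted p = 0.00233; adjusted p = 0.401 with an estimated correlation), which was lost without pair 2 (0.258).

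Among stress genes both copies of cyclin G1, a target of the p53 tumour suppressor, rose. ccng1.L was at 133, 29.3 and 16.3 CPM in controls 1 to 3 and at 254, 87.3 and 44.0 CPM in the dkk siblings, a rise in every pair although the pairs differed widely (log2 fold change 1.31 ± 0.15, SE; adjusted p = 0.0118, edgeR with Benjamini-Hochberg adjustment). ccng1.S rose by 1.44 ± 0.18 (adjusted p = 0.0156). Outside the lists, eda2r-like.1, named after another p53 target, rose from 4.96 ± 2.75 CPM to 14.4 ± 8.02 CPM, rbl2-like.L by 1.90 on the log2 scale and cebpa.1 from 38.9 ± 7.09 CPM to 99.0 ± 40.0 CPM (SD, n = 3). Both ccng1 copies were the 2 that rose among 42 tested stress genes; 0 fell and 40 did not pass, and 11 rose and 1 fell when adjusted over the list alone. The sestrin copies sesn1.L and sesn1.S, at 1.52 ± 0.27 and 1.22 ± 0.21, had adjusted p-values of 0.0728 and 0.0662 (edgeR with Benjamini-Hochberg adjustment). The list lay higher (camera, adjusted p = 8.67e-15; adjusted p = 0.182 with an estimated correlation and 0.0886 with fry). Calls of ccng1.L, eda2r-like.1, rbl2-like.L and cebpa.1 were lost without pair 2, and those of ccng1.S, eda2r-like.1 and rbl2-like.L without pair 1.

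Interferon and RNA-sensing genes gave 0 calls among 13 tested with edgeR, DESeq2 and limma-voom, with 1 lower at an unadjusted p under 0.05, and the list was not past the threshold (camera, adjusted p = 0.725). Maternal and germ plasm genes gave 0 of 31 with each tool, with 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.859), though without pair 3 the list lay lower at 0.00407 and without pair 2 higher at 0.0320. The maternal list's median was -0.05 and its mean 0.08, so they differ in sign. Housekeeping genes gave 0 of 24 with each tool and 1 higher and 1 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.730). Median and mean also differed in sign in the interferon list (0.03 and -0.03) and the housekeeping list (-0.02 and 0.01). Ribosomal protein genes also had 0 of 53 past the threshold with each tool and 8 higher at an unadjusted p under 0.05. Their median log2 fold change was 0.19, with medians of 0.345, 0.241 and -0.0234 in pairs 1 to 3. That list nevertheless lay higher (camera, adjusted p = 5.76e-13 with a preset correlation; adjusted p = 0.5003 with an estimated correlation). Over the 19 lists, 14 passed with the preset correlation, 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and 2 with fry. The lists that passed with fry, which asks only whether a list's genes move on balance in 1 direction, were Wnt feedback and retinoic acid (adjusted p = 0.00637 each).

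**Figure D3:**
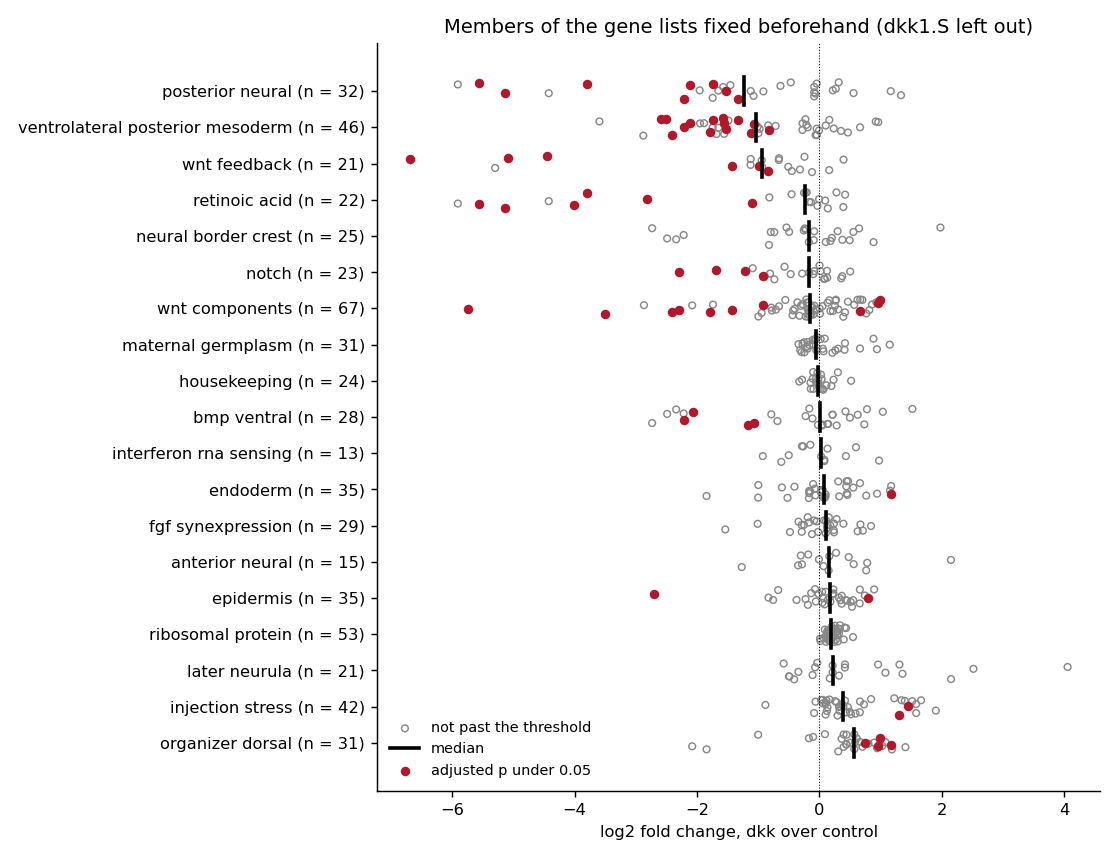
Log2 fold change of dkk over control embryos for each tested member of the 19 fixed gene lists, with dkk1.S left out. Filled red points passed an adjusted p of 0.05 (edgeR), open points did not, and black bars are medians, which run from -1.23 in the posterior neural list to 0.57 in the organizer list.

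The sibling pairs were compared with each other. Across all 21643 genes the log2 ratios of pairs 1 and 2 correlated at r = 0.396, those of pairs 1 and 3 at 0.130 and those of pairs 2 and 3 at 0.0456. Over the 123 genes past the threshold other than dkk1.S the values were 0.954, 0.928 and 0.922, on genes chosen for their agreement between pairs. These correlations are across genes, which are not independent replicates.

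The authors' deposited table lists 97 genes, 15 higher and 82 lower in dkk embryos, each with an absolute log2 fold change of at least 1.02. All 97 were tested here and had the same direction, and 60 of them passed the threshold. A further 64 genes passed here that the authors' deposited table does not list, 45 of them with an absolute log2 fold change over 1. For the 97 genes the median absolute log2 fold change was 1.34 in the authors' deposited table and 2.29 in the paired fit. These are unlike measures. The authors' values lay a median of 0.00539 from an unpaired DESeq2 fit with a shrinkage prior, and the paired edgeR fit used no such prior. The fold changes of the 45 genes are likewise those of the paired fit. Both were made from the same 6 libraries, so the overlap is not independent evidence.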

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

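The fit of DESeq2 with a shrinkage prior and no block, the lists without dkk1.S and the between-pair agreement under other settings were tests chosen only after the result was seen. With the pairing left out (no mating pair block) 14 genes passed, 1 higher and 13 lower, and 14 of the authors' 97 genes. The DESeq2 Wald test with the block called 391 genes (124 higher, 267 lower) and 94 of the authors' genes; without a filter on low counts 343 passed (112 and 231), with 96.8% of the same sign in all pairs. glmTreat called 10 higher, and with L and S copies summed, which tests fewer genes, 66 fell. The added unpaired DESeq2 fit called 113 genes, 71 of them among the 124, and 96 of the authors' genes. Leaving out 1 pair gave 58 to 659 genes, 6 to 332 higher, 52 to 327 lower and 39 to 84 of the authors' genes; 98, 49 and 118 of the 124 were kept without pairs 1, 2 and 3. Under RLE, upper-quartile, limma-voom and stricter-filter settings 122 to 141 genes passed, at least 122 of them among the 124. Where tested (123 of the 124 under the stricter filter, all elsewhere), they kept their direction under every setting that kept single copies. Camera with an estimated correlation called 0 lists and fry 2; with copies summed 10 of the 14 lists were kept, the Bmp (adjusted p = 0.2496), epidermis (0.134), neural border (0.0965) and Wnt pathway (0.07996) lists being lost with camera. The epidermis list was also lost without the block (0.256) and with DESeq2 (0.120), which kept the other 13. Directions turned in genes that were not past the threshold and in 5 lists, of which the Bmp and endoderm lists had passed with camera and turned without pair 3. With copies summed dkk1.L, merged with dkk1.S, stood at 4.19, and the maternal list was higher at an adjusted p of 0.816. Leaving out 1 pair, log2 fold changes ranged from -0.34 to 0.13 for gbx2.2.S, -0.0699 to 1.52 for gsc.L, -0.26 to 0.13 for wnt8a.L and -0.27 to 0.22 for wnt8a.S. In the same fits camera's adjusted p ranged from 2.74e-08 to 0.413 for the Bmp list, 2.71e-08 to 0.283 for the endoderm list, 0.283 to 0.850 for the Fgf list, 0.00407 to 0.131 for the maternal list and 0.159 to 0.718 for the housekeeping list. Of 57 named genes past the threshold, 10 were kept without the block, 51, 31 and 53 without pairs 1, 2 and 3, 47 by glmTreat and 52 with copies summed. List tests under limma-voom and glmTreat were not run. The cause of these differences was not tested.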

Other observations

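Chosen only after the result was seen were the test for embryos injected with another mRNA, the test of the knockdown on the Wnt feedback list and the homeolog values without dkk1; the patterns themselves were picked from an exploratory fit.

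The L and S copies of a gene were compared with each other. They were read in the same 6 embryos, so differences between embryos move both copies, and the shares and correlations given here have no value without a dkk effect to be set against. Among 4549 genes with both copies tested, 19 had both copies past the threshold, all in the same direction, 14 the L copy alone and 17 the S copy alone. The 2 copies had the same sign in 96% of the 50 genes with a copy past the threshold and in 62.5% of all. Log2 fold changes correlated at r = 0.663 over the 50 genes and 0.499 over all, or 0.788 over 49 and 0.521 without dkk1. The ratio of L to S was tested with limma on the difference of their log2 CPM, with the mating pair as a block. It changed in 12 genes after Benjamini-Hochberg adjustment, 6 of them among the 50 and dkk1 counted in both. At an unadjusted p under 0.05 (limma) it changed in 395 genes. kremen2, which encodes a Dickkopf receptor, had a ratio change of -3.05 ± 0.40 (SE, limma, adjusted p = 0.0437). The edgeR log2 fold changes were -5.74 in kremen2.L and -2.30 in kremen2.S.

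Of 23456 untested genes, 87 had reads in every dkk embryo and in no control, and 82 had reads in every control and in no dkk embryo.

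The real grouping of the 6 embryos gave 124 genes, and the highest other split gave 0. Of the 10 splits into 3 and 3 only 4, the real 1 among them, part all 3 sibling pairs; the other 6 part 1 pair and are no reference for the paired test. With 4 splits the share of the real one cannot fall below 0.05, so a chance split stays open. At an unadjusted p under 0.05 the 3 other splits that part all pairs gave 216 to 2423 genes, the highest above the 1693 of the real one.

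Both ccng1 copies and eda2r-like.1 rose in all 3 dkk embryos. Of 26 interferon and RNA-sensing rows, 13 were tested, with a median log2 fold change of 0.0291 (95% interval -0.285 to 0.133). This argues against an innate response to introduced RNA that raises the 13 as a set. A rise of a few genes, or of those the filter left out, is not covered. The 95% intervals here and in the next paragraph resample genes, not embryos. A rise of p53 targets as a group fits: over 16 genes without ccng1 and eda2r limma's fry, which assumes normal errors, gave p = 0.0238, a level an exact permutation of 3 pairs cannot reach. Singly, 0 of these passed with edgeR, 7 were higher at an unadjusted threshold of 0.05, DESeq2 called 2 and limma-voom 0. Open stay a general stress response, with a median of 0.337 over 22 heat shock, unfolded protein and immediate early genes (0.119 to 0.466), and injection of any mRNA rather than dkk activity, as 0 libraries of embryos injected with another mRNA were analysed here.

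The organizer gene gsc was far higher in dkk embryo 3 than in its sibling, at log2 ratios of 2.58 for gsc.L and 2.09 for gsc.S. A stronger Wnt knockdown in that embryo stays open: pair 3 less the mean of pairs 1 and 2 had a median of -0.00386 (95% interval -0.185 to 0.630) on the Wnt feedback list, -0.00685 (-0.237 to 0.410) on the retinoic acid list, -0.0994 (-0.463 to 0.0857) on the Wnt pathway list and -0.438 (-0.786 to 0.000240) on the posterior neural list, but -0.756 (-1.12 to -0.416) on the ventrolateral and posterior mesoderm list and -0.872 (-1.28 to -0.564) on the Bmp list, the 2 lowest of 19. On genes called lower the median was -0.0267 (-0.150 to 0.0889), but that test is void because the paired test picks genes that move alike in all pairs, and dkk1.S was highest in dkk embryo 3, at 725 CPM. Another developmental time of that embryo also stays open: maternal less later neurula genes shifted by 0.918 (0.0117 to 1.94), the maternal genes by 0.771 (0.319 to 0.987) and the neurula genes by -0.147 (-1.13 to 0.566), but their medians lay closer in pair 3 (0.42 and 0.23) than in pair 2 (-0.33 and 0.64). A biological difference between the matings was not tested.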
